A study of Mus musculus with 307 samples.

How the data were processed

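Expression was measured by sequencing of poly-A RNA in 143 libraries and factor binding by ChIP sequencing in 83 libraries, all from mouse T cell cultures. The series lists 307 samples. Input libraries and libraries of open chromatin came without files and were not analysed, and neither were merged peak clusters or network scores built by the authors from the same libraries. Groups follow the labels: culture, hours, line or siRNA, and genotype. Some RNA libraries were made with Nextera per the labels, which do not say which ones.

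Per the labels the authors used Bowtie 0.12.7, TopHat 1.2.0, Cufflinks 0.9.3, HTSeq 0.5.3p3, MACS and DESeq (no version given for the last 2) on mouse build mm9, without stating which step each tool served. The RNA files hold FPKM per gene locus as deposited by the authors, 1 file per library, in the layout of Cufflinks gene output. The ChIP files hold, per the file headers, a MACS score per peak (minus 10 times the log10 of p) beside its fold enrichment and FDR. Each ChIP list was called by the authors against a control library and holds only peaks assigned to genes, as summit positions without widths. The score ran from 100 to 3233.06, and 1.48% of peaks could be given no chromosome from the assigned gene. The 29 comparison tables of the authors hold mean read counts per group (the deposited signal), scaled by size factors in most of them. They also hold the log2 ratio of control over knockout or siRNA and a p-value with an adjusted p-value, all as deposited by the authors.

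Of the columns in these tables, 145 were used and 261 were not. No file gives read counts per library. Depth and counting error per library are therefore unknown, and no interval or detection limit was computed from counts for the RNA values. FPKM summed to between 251577 and 427500 per library, and 7598 to 11258 genes were listed at 0. Values with the status FAIL (24 to 82 genes per library, 248 genes in any library) were treated as missing. Foxp3 failed in 60 libraries and Crem in 82. Each file holds 22281 loci of 21858 gene names, and the loci of 218 names with more than 1 locus were summed.

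FPKM values were rescaled within each fit by the median of ratios to the gene means, and log2(FPKM + 1) was analysed with limma 3.58.1 in R 4.3.3 (linear models, empirical Bayes with a trend). Genes with a mean of at least 1 in the libraries of a fit were tested, two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Th17 was compared with Th0 at 48 h over the controls of all lines and wild-type cells, with line as a covariate. The 7 knockout lines were fitted together with 1 mean per line, genotype and culture. That fit gave the knockout effect in each culture and the difference of the effects. In it a library left alone in its group after another was left out is assumed to vary like the others. Th1, Th2 and iTreg were compared with the 16 control and wild-type Th0 libraries of 48 h, without a term for line. The screen was fitted over its 49 libraries with the codes in the labels as a block, and the RPMI set over its 10 libraries. Own targets in the screen were adjusted over the 19 measured targets. Each code held at most 1 siNonTarget2 library, and the code 120309 held none. That code was carried by replicate 2 of siId2, siSki, siAtf6, siTrib3, siPrkrir and siSatb1 and by siRorc replicate 4. These libraries have no control in their block.

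The 20 gene lists were tested with camera, with a correlation estimated from the residuals, and also with a preset correlation of 0.01. Over 31 comparisons and 504 list tests, 28 were called with the estimated correlation and 153 with the preset, the 28 among them. Set adjusted p-values in the report come from the estimated correlation unless stated. Genes raised in Th17 by at least 1 on the log2 scale in the other lines' controls formed the set tested in each knockout.

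Genes named in the text were taken from those that a fixed rule allows. The rule holds the target gene, the members of the Th17 list, and up to 6 rises and 6 falls. These are the largest called changes, with a mean of at least 5 in the higher group and libraries of the 2 groups that do not overlap. It also holds up to 4 called members of any other list described, the 8 loci of the peak survey, and 10 effector genes with the own target in the screen. Which of the genes allowed by the rule are given was decided after their values were seen, mostly in favour of calls that held without any 1 library. Of 181 named gene results 157 were called, and 123 of these were called in every fit without 1 library. Genes of the time course and all genes of the smallest counts were named after their values were seen.

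A control peak counted as found when the other list had a summit within 100 bases. Overlap by 1 base, the measure set out at first, could not be computed without peak widths. The 1000 highest control peaks by score were taken, and 3000 per library for overlaps between factors. Wilson intervals (95%) are given where a group had 1 library. Genes changed in a knockout were compared with the other tested genes for peaks of the factor in all wild-type Th17 libraries by Fisher's exact test in scipy 1.17.1, adjusted over the 7 factors. Of 19617 genes with a peak in any list, 754 had no RNA locus and were left out. Tables were read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and figures drawn with matplotlib 3.10.9.

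Alternatives were a pseudocount of 0.1, no filter on low values, values as deposited without rescaling, quantile normalization, fits over a comparison's own libraries, no code term, the library series as a block (13 runs of library numbers), the replicate number as a block in the RPMI set, other numbers of peaks, and leaving out each library in turn. Other summit distances, p300 ko lists at one length, a fit of the Th17 libraries alone, lists without the deleted gene itself, and leaving out the libraries labelled Th0 Maf ko replicate 2 and Th0 Irf4 control replicate 2 were added after the data were seen. The procedures were tested on simulated data made from the real libraries with changes added to 100 genes of each size. The changed genes were drawn only from genes with means well above the minimum of 1 FPKM for testing. Recovery of tested genes near that minimum was therefore not measured, and the rates below do not cover them. At a log2 change of 1 the fits recovered 51% of changed genes for a difference between cultures, 74% at 16 h, 76% for a knockout in Th17 and 99% for Th17 against Th0. At a log2 change of 2 they recovered at least 95%, and 4 to 17 unchanged genes were called. The simulated libraries had the real gene means and spreads with independent normal noise. They held no line, code or series effects, no correlation between genes and no library that lay apart. These rates therefore do not cover errors from such sources in the real libraries.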

Results

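The series profiled mouse naive CD4 T cells cultured under non-polarizing conditions (Th0) or under conditions that polarize toward Il17a-producing helper cells (Th17). RNA was sequenced in 143 libraries of 75 groups, and transcription factors, cofactors and histone marks were mapped by chromatin immunoprecipitation (ChIP) in 83 libraries of 54 groups. The knockout (ko) arm held 7 lines with 2 libraries for each genotype and culture at 48 h, and an Ikzf3 line with 1 library each. Wild-type Th0 and Th17 cells had 3 libraries each at 16 h and 1 library at every other time. Th1, Th2 and iTreg cultures had 2 libraries each. A siRNA screen at 24 h held 20 siRNAs and 6 libraries of the control siNonTarget2, and a second siRNA set, labelled RPMI, held 4 siRNAs and the control siCntl with 2 libraries each. The RNA files give fragments per kilobase and per sequencing depth (FPKM) and no read counts, so depth and counting error per library are unknown. A median of 10041 genes per library (9200 to 10635) reached 1 FPKM. The authors' comparison tables list mean counts per group that sum to between 12730723 and 28307298. ChIP peak lists held 85 to 53290 peaks assigned to genes, with a median of 12519. Values below are mean FPKM ± SD after rescaling unless stated, positions refer to mouse build mm9, and p-values measure only the spread between these libraries.

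The first question was which transcripts distinguish Th17 from Th0 cells at 48 h. The cytokine transcripts rose furthest. Il17a (chromosome 1, 20720986 to 20724577) reached 616 ± 325 in Th17 (n = 16) against 18.4 ± 25.6 in Th0 (n = 16). Il17f (chromosome 1, 20767230 to 20774351) reached 1714 ± 466 against 53.1 ± 61.3, and Il21 (chromosome 3, 37121681 to 37131540) 180 ± 32.4 against 5.45 ± 5.85. Receptor and regulator transcripts rose with them: Il23r (chromosome 6, 67372926 to 67441849) by 4.09 on the log2 scale (adjusted p 1.44e-17), Maf (chromosome 8, 118227153 to 118230794) by 4.29 (adjusted p 8.05e-17) and Rorc (chromosome 3, 94176748 to 94202161) by 2.05 (adjusted p 1.44e-14). Hif1a rose by 1.55, Fosl2 by 1.44, Batf by 0.96 and Irf4 by 0.72. Ccr6 did not differ (log2 change -0.21, adjusted p 0.217). Among the largest falls were Penk (-4.51), Wisp1 (-3.92) and Ms4a4b (-3.80). In the limma fit with line as covariate, 6203 of 10591 genes passed an adjusted p of 0.05, 3151 higher and 3052 lower, and 605 of them changed at least 2-fold. Leaving out each line in turn gave 5603 to 6170 genes.

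Of 22 Th17 genes listed before the data were examined, 21 rose, the exception being Ccr6. All 8 genes of the transforming growth factor beta list rose, as did 9 of 10 genes of the interleukin 6 and Stat3 list, 10 when adjusted over the list alone. Set tests with an estimated correlation called the Th17 list (adjusted p 0.00673) and the transforming growth factor beta list (adjusted p 0.0214) and no other. With a preset correlation the interleukin 6 (adjusted p 1.42e-06), glycolysis (1.39e-05), cholesterol synthesis (6.49e-05) and unfolded protein (0.0105) lists were called as well. In these, 20 of 22 glycolysis genes and 13 of 19 unfolded protein genes rose, with 1 of the latter lower, and 12 of 16 cholesterol genes fell and 1 rose. The remaining lists went both ways or hardly moved, as higher and lower genes: Th1 5 and 6 of 12, Th2 3 and 4 of 8, Treg 6 and 3 of 10, follicular helper 3 and 3 of 7. Counts were 6 and 6 of 13 for resting genes, 4 and 9 of 15 for early activation, 4 and 3 of 12 for interferon response, and 4 and 4 of 19 for cell cycle. No histone gene rose and 5 of 10 fell. The B cell list had 2 higher and 2 lower of 4 (Cd74 by -1.77 and H2-Ab1 by 1.20 among them), 1 of 2 natural killer and CD8 genes fell (Cd8b1 by 0.38), the 1 myeloid gene was not called, and no erythroid or gamma delta T cell gene was measured. Counts adjusted over the list alone were equal for all lists but the interleukin 6 list.

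At 16 h several regulators already differed, while Il17a and Irf4 were not called. Rorc stood at 119 ± 11.9 in Th17 (n = 3) against 6.60 ± 2.50 in Th0 (n = 3), Maf at 169 ± 17.5 against 3.00 ± 3.65, Batf at 197 ± 40.5 against 28.2 ± 5.16 and Ahr at 67.0 ± 6.47 against 3.46 ± 1.19. Il21 rose by 5.42 (adjusted p 0.00151) and Il17f by 5.26 (adjusted p 0.0115), but Il17a stood at 4.48 ± 4.71 in Th17 and was not called (log2 change 1.14, adjusted p 0.418), nor was Irf4 (0.20, adjusted p 0.514). Stat4 fell by 2.73, Gata3 by 2.21 and Cd226 by 4.54, while Cxcr5 rose by 3.07, Bcl6 by 1.73 and Tbx21 by 1.99. Markers of other cell types moved in the same comparison: Cd8b1 stood at 2.10 ± 0.485 in Th17 against 26.1 ± 2.98 in Th0 (adjusted p 6.07e-05), Cd74 fell by 1.79 (adjusted p 0.0089) and Nkg7 by 1.41 (adjusted p 0.0493, lost without any library but Th0 replicate 1). In total 1812 of 9788 genes were called, 889 higher and 923 lower. Replicate 1 of Th17 and replicate 1 of Th0 came from different library series, which the fit did not model. The count was 970 without Th17 replicate 2, 1123 without Th17 replicate 3 and 1074 without Th0 replicate 3, and up to 1646 without another library. Of the 9671 genes tested at both times, 612 were called higher at both, where 252.8 were expected by chance, and 556 lower at both, where 262.5 were expected. Another 202 genes were called in opposite directions. The Th17 list had 14 of 17 genes higher and the transforming growth factor beta list 7 of 7, with estimated-correlation adjusted p of 0.128 and 0.379.

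Single wild-type libraries give the order of onset in Th17 cultures, in FPKM as deposited and without replicate error. Batf stood at 158 FPKM at 1 h against 13.6 in Th0, and Socs3 at 222 against 24.9. The Th17 and Th0 libraries at 1 h came from different library series (1 and 2), so culture and series cannot be told apart there. Maf was 18.0 at 1 h, peaked at 193 at 12 h and was 31.2 at 48 h. Rorc was listed at 0 at 1 h, reached 118 at 12 h and 51.5 at 48 h. Il17f passed 26.9 at 9 h, 81.0 at 12 h and 2065 at 24 h. Il17a stood at 1.16 at 12 h, 67.0 at 24 h and 857 at 48 h.

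**Figure D1:**
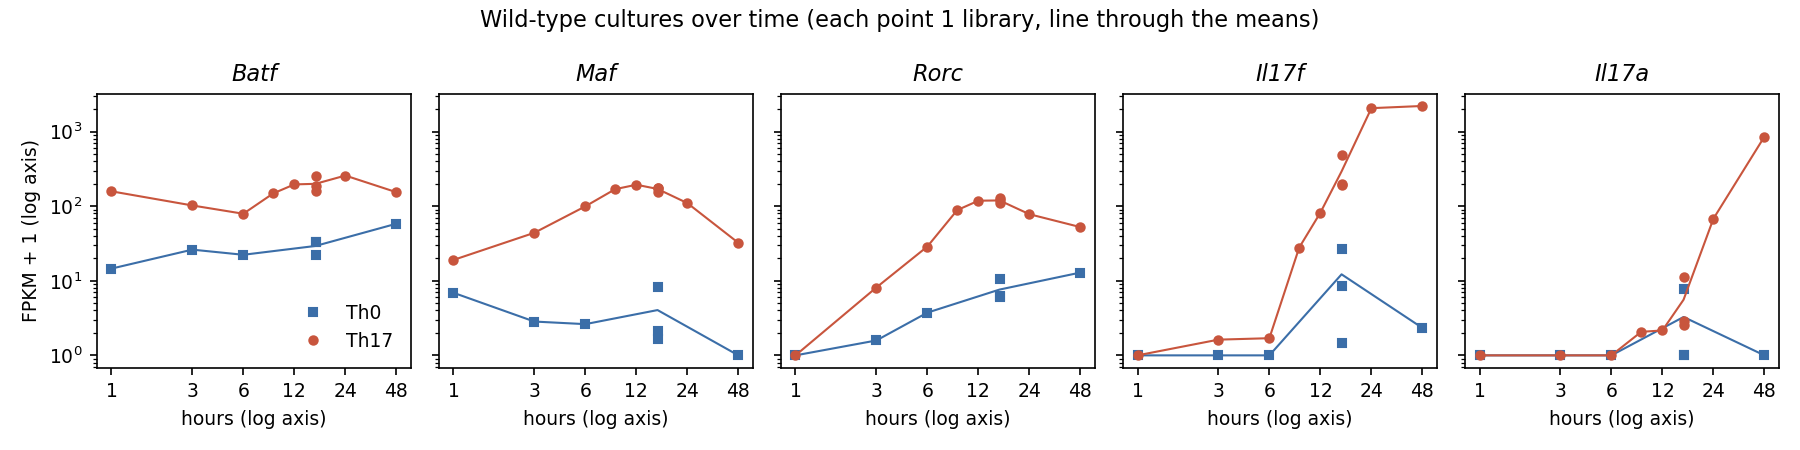
FPKM as deposited (plus 1, log axis) of Batf, Maf, Rorc, Il17f and Il17a against hours in culture, 1 point per wild-type library, Th0 and Th17 in separate colours. Maf and Rorc are highest at 12 to 16 h, Il17f at 24 to 48 h and Il17a at 48 h.

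The knockout lines ask which part of the Th17 programme needs each regulator. All 7 lines were fitted together (10568 genes tested), so the spread is shared between lines. In each comparison 528 genes were expected by chance at an unadjusted p under 0.05. Where fewer had one, few calls do not show that few genes changed. Ranges of counts without 1 library below leave out libraries of the comparison itself. That fit includes the library labelled Th0 Maf ko replicate 2, whose Th17-raised genes lay 95.2% of the way from the Th0 to the Th17 Maf control. Without it, a fit chosen after the data were seen, the difference between cultures called 51 genes for Batf, 178 for Irf4, 393 for Stat3 and 29 for Fosl2. Ko and control libraries of a replicate share a series of library numbers, except in Stat3 replicate 2. With that series as a block, Th17 counts were 1.0e+03 (rounded) for Batf, 1875 for Irf4, 2385 for Stat3, 21 for Rorg, 20 for Maf, 2050 for Fosl2 and 489 for Hif1a. The difference between cultures then called 95 genes for Batf, 378 for Irf4, 663 for Stat3, 8 for Maf and 113 for Fosl2. In fits of a comparison's own libraries Irf4 ko called 2 genes in Th17, 73 in Th0 and 0 for the difference, and Fosl2 ko 1571 in Th17. Per the labels Rorg ko is a GFP knock-in, and Irf4, Batf and Ikzf3 ko are -/-. Stat3, Maf, Fosl2 and Hif1a ko are floxed with CD4-Cre, and their controls carry CD4-Cre too. How complete the deletion by Cre was is not given. The labels do not give which part of a gene each knockout deletes, so FPKM over the whole gene does not check the deletion.

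Stat3 ko called the most genes of the 7 lines in Th17 by the pooled fit. In Stat3 ko Th17 cultures Il17a stood at 0.205 ± 0.290 against 737 ± 113 in the control (n = 2 each; log2 change -9.27, adjusted p 0.000232), and Il17f at 0.653 ± 0.924 against 1865 ± 267. Il21, Il23r, Il1r1 and Timp1 were listed at 0 in both ko libraries, against control means of 176, 23.7, 14.0 and 76.6. The regulators fell too, with log2 changes of -4.58 for Rorc, -4.66 for Maf, -3.45 for Rora, -3.20 for Fosl2 and -1.39 for Hif1a. Transcripts of Th1 cells and of the interferon response rose, with Ifng at 544 ± 50.7 against 8.04 ± 11.4 (adjusted p 1.44e-08), Ccl3 up by 4.77, Eomes by 4.01 and Stat1 by 1.72. Markers of other cell types moved with them, with Nkg7 at 182 ± 42.7 against 3.82 ± 1.88 (adjusted p 2.61e-06) and Cd74 up by 2.21, while Ebf1 fell by 1.84 and H2-Ab1 by 2.88 (adjusted p up to 0.13 without control replicate 1 or ko replicate 2). Stat3 itself stood at 15.4 ± 2.10 against 135 ± 9.56. In Th17, 1493 genes were called, 556 higher and 937 lower, with 700 without control replicate 1, 731 without ko replicate 2 and 993 without ko replicate 1. In Th0 only Stat3 (lower) and AA465934 (higher) were called, with 104 genes at an unadjusted p under 0.05, and AA465934 was lost without ko replicate 1 or control replicate 2 (adjusted p up to 0.182). The ko effect differed between cultures for 253 genes (110 to 168 without any 1 of its 8 libraries, 393 without the library labelled Th0 Maf ko replicate 2), among them Rorc (difference -4.34, adjusted p 0.000191), Il23r (-4.62), Fosl2 (-2.81), Itga3 (-5.08) and Iigp1 (4.18). Of the Th17 list 17 of 22 genes fell, Stat3 itself among them, 20 when adjusted over the list alone (set adjusted p 0.0303). Without Stat3 the list was not called (16 of 21, 19; 0.0561), but it was in the difference between cultures (0.0322). Rises were called for 7 of 14 Th1 genes (7; 0.000823) and 10 of 13 interferon genes (12; 0.0249). The set tests of the difference between cultures called the same 3 lists (adjusted p 0.0345, 0.000181 and 0.00527). For Il17a the difference between cultures was -9.39 (adjusted p 0.0256), and it was no longer called without any 1 of the 8 libraries (adjusted p 0.0612 to 0.114).

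Irf4 ko changed genes in both directions in Th17 cultures. Ccr6 fell from 68.0 ± 19.9 to 7.70 ± 1.07 (n = 2 each; adjusted p 3.47e-07), Satb1 fell by 1.62 and Ctla4 by 2.39. Nrp1 rose from 1.67 ± 0.140 to 48.2 ± 1.56 (adjusted p 3.07e-10), and Nt5e rose by 4.06 (to 74.3 ± 60.2), Lrrc32 by 2.86 and Sell by 2.88. Cholesterol synthesis genes rose, with Hmgcr at 126 ± 0.101 against 67.1 ± 2.11 and Insig1 up by 0.83. Irf4 itself stood at 22.0 ± 13.7 against 281 ± 17.2. Of other cell type markers Nkg7 rose by 4.23 (89.5 ± 95.6 against 2.29 ± 1.12, not called in a fit of the 4 libraries alone) and by 4.34 in Th0, and Ebf1 fell by 1.00 (not called without either control library or ko replicate 2, adjusted p up to 0.366). Il17a stood at 45.9 ± 4.28 against 788 ± 224 and Il17f at 137 ± 32.0 against 1771 ± 509, neither of them called (adjusted p 0.158 and 0.245). In a fit of the Th17 libraries alone, chosen after the data were seen, Il17a (adjusted p 9.38e-05) and Il17f (9.71e-06) were called. Il23r fell by 2.83 (adjusted p 0.0073) and Rorc by 1.77 (adjusted p 0.0189), but without control or ko replicate 2 neither was called, nor was Rorc without control replicate 1 (adjusted p up to 0.104 and 0.547). The 2 ko libraries differed, with Rorc at 29.2 and 6.72 in replicates 1 and 2, Il21 at 79.6 and 13.9, Gata3 at 6.13 and 33.7 and Foxp3 at 8.08 and 32.5, looked up after the data were seen. Th0 ko replicate 2 stood above Th17 ko replicate 2 in most genes of the Th17 list, among them Il17a (66.1 against 42.9), Il17f (179 against 115) and Rorc (12.8 against 6.72). It stood below in Ahr (3.79 against 16.4), Ccl20 (1.93 against 2.70) and Il12rb1 (10.3 against 12.7). Over genes raised in Th17 these libraries lay 37.2% (Th0) and 41.3% (Th17) of the way from the Th0 to the Th17 Maf control. Over genes lowered in Th17 they lay at 15.3% (Th0) and 36.9% (Th17). An exchange of culture labels was not tested. In Th17, 865 genes were called, 419 higher and 446 lower, with 1392 without ko replicate 1, 472 to 565 without any other, and 2 in a fit of the 4 libraries alone. In Th0, 351 genes were called, 184 higher and 167 lower (153 without ko replicate 1, 268 without control replicate 2, which had the highest Gata3 and Il13 of the Th0 libraries), and Xcl1 stood at 71.9 ± 14.1 against a control listed at 0. The ko effect differed between cultures for 58 genes (288 without Th17 ko replicate 1, 89 without Th17 ko replicate 2, 27 without Th17 control replicate 2, and 34 to 36 without Th0 ko replicate 1 or 2 or Th0 control replicate 2, but 0 in a fit of its own 8 libraries), among them Nrp1 (3.62) and Fgf2 (3.95). The cholesterol list was called in Th17, with 6 of 16 genes higher, 9 when adjusted over the list alone (set adjusted p 0.026), and in the difference between cultures (0.0116). Of the Th17 list, 9 of 22 genes were lower, 14 when adjusted over the list alone (8 and 13 of 21 without Irf4 itself). In Th17 the Treg list had 4 higher and 1 lower of 11 genes (6 and 1; set adjusted p 0.0668) and the resting list 3 and 3 of 13 (3 and 4; 0.843), neither called as a set.

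Batf ko lowered some genes of the Th17 list, and a few interferon genes rose. Il23r fell from 51.7 ± 2.77 to 1.07 ± 0.0703 (n = 2 each; adjusted p 4.65e-05), Ahr from 24.3 ± 2.46 to 2.20 ± 0.341 and Ctla4 from 1340 ± 83.7 to 233 ± 40.3. Iigp1 rose by 3.99, Angptl2 by 3.92, Cd80 by 3.62 and Stat1 by 1.19. Of other cell type markers Cd74 rose by 2.70 and Ebf1 fell by 1.42 (adjusted p 0.0645 without control replicate 1). Batf itself stood at 1.35 ± 0.801 against 90.5 ± 10.9. Il17a fell from 354 ± 74.6 to 1.90 ± 0.262 (adjusted p 0.0141), a call lost without any 1 of the 4 libraries (adjusted p 0.0765 to 0.16), and Il21 was not called (-0.71, adjusted p 0.947). In a fit of the Th17 libraries alone, chosen after the data were seen, Il17f (adjusted p 2.63e-05) and Rorc (0.0205) were called lower as well. In Th17, 384 genes were called, 153 higher and 231 lower (113 to 211 without any 1 library). In Th0 there were 53 calls, 38 higher and 15 lower (14 to 32 without 1 library), with Iigp1 3.23 higher. The difference between cultures called 12 genes, 7 higher and 5 lower (0 to 4 without 1 of its 8 libraries, 51 without the library labelled Th0 Maf ko replicate 2). The interferon list was called in Th0, where 4 of 13 genes rose, 12 when adjusted over the list alone (set adjusted p 8.76e-05), but not in Th17, where 2 of 13 rose (2; 0.646). The Th2 list was called in Th0 too, with 1 of 8 lower (2; 0.034). In Th17 the cholesterol list was called, with 3 of 16 genes higher (4; 0.0481). The Th17 list had 6 of 22 genes lower in Th17, 8 when adjusted over the list alone (5 and 6 of 21 without Batf itself), and was called as a set with the preset correlation alone (2.54e-11).

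Rorg ko, which targets the isoform of Rorc in T cells, had few genes called by the pooled fit although cytokine means fell far. Il17a stood at 34.8 ± 11.0 against 839 ± 376 (n = 2 each; log2 change -4.51, adjusted p 1), Il17f at 326 ± 84.4 against 1896 ± 602 and Il23r at 4.00 ± 0.517 against 20.2 ± 1.21 (adjusted p 0.837). Il21 stood at 187 ± 56.0 against 194 ± 57.0. In a fit of the Th17 libraries alone, chosen after the data were seen, Il17a (adjusted p 0.000385), Il17f (0.00557) and Il23r (0.00135) were called. In the pooled fit 321 genes had an unadjusted p under 0.05 in Th17, fewer than the 528 expected by chance. The fit called 7 genes in Th17, all lower. They were Cxcl3, listed at 0 against 15.3 ± 0.608 (adjusted p 0.00158), 2310007L24Rik, Fam124b, Fes, Lysmd2, Mast4 and Vax2. Cxcl3 alone was called without any 1 library, and the count was 2 without control replicate 2 and 3 without ko replicate 2. In Th0 Lysmd2 alone was called (log2 change -1.29, adjusted p 0.0337), and it was lost without any 1 library. No gene was called by limma for the difference between cultures, with 58 at an unadjusted p under 0.05, and 1 was called without Th0 ko replicate 1 or Th17 control replicate 1. The early activation list was called as a set in Th0 (adjusted p 0.0443), with 0 of 15 genes past the threshold either way. Rorc over the whole gene stood at 25.7 ± 1.43 against 44.0 ± 1.13, not called.

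Maf ko had 2 called genes in Th17, Maf and Klhdc4, both on chromosome 8 (from 118227153 and from 124320208). Whether Klhdc4 changed through loss of Maf or through a variant linked to Maf was not tested. In the 2 ko libraries Maf itself stood at 10.3 and 0. Maf stood at 5.14 ± 7.27 against 56.0 ± 32.1 (n = 2 each; adjusted p 0.0466), a call lost without either control library or ko replicate 2 (adjusted p up to 1), and Klhdc4 fell by 0.94 (adjusted p 7.93e-05). Il22 was 3.39 higher, not called (adjusted p 0.29), and was called with the library labelled Th0 Maf ko replicate 2 left out (adjusted p 0.000306). In Th17 251 genes had an unadjusted p under 0.05, with 5 called without ko replicate 1, 1 without ko or control replicate 2 and 18 without the library labelled Th0 Maf ko replicate 2. In Th0 11 genes were called, with 0 without ko replicate 2, 933 without ko replicate 1, 31 without control replicate 1 and 3 without control replicate 2. The difference between cultures called Ifih1 and Cd274, named after their values were seen, with 511 genes without Th0 ko replicate 1, 7 without Th0 control replicate 1 and 0 without any other library but Th17 control replicate 1. The Th1 list was called as a set in Th17 (adjusted p 0.000278), with no gene past the threshold over all genes and 5 when adjusted over the list alone.

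Libraries labelled Fosl2 ko differed widely from their controls in Th17, but not in Fosl2 itself, which stood at 90.8 ± 13.7 against 78.5 ± 7.33 (n = 2 each; log2 change 0.20, adjusted p 0.806). Serpinb1a fell from 14.4 ± 6.36 to 0.268 ± 0.0449 (adjusted p 9.26e-08), Gipr by 3.26 and Itga7 by 3.41, and Il24 was listed at 0 against 15.4 ± 8.08. Tbx21 rose from 4.30 ± 1.46 to 19.1 ± 2.56 (adjusted p 0.0315) and Il2 from 108 ± 34.5 to 414 ± 135 (adjusted p 0.00782), but Tbx21 was not called without any 1 of the 4 libraries (adjusted p up to 0.275), nor Il2 without control replicate 1 or ko replicate 2 (up to 0.202). Il17a was not called (log2 change 1.82, adjusted p 0.621). Of other cell type markers Nkg7 was 2.89 higher and Cd68 0.87 lower, both lost without 1 library (adjusted p up to 0.118 and 0.256). In Th17 694 genes were called, 290 higher and 404 lower, with 86 without ko replicate 2 and 183 to 325 without any other. With values as deposited 59.3% of the calls were higher, against 41.8% after rescaling. In Th0 6 genes were called (2 without ko replicate 1 or control replicate 2), and the difference between cultures called 9 (2 to 4 without any of its 8 libraries but Th0 ko replicate 2, 29 without the library labelled Th0 Maf ko replicate 2), among them Serpinb1a (-3.34) and Gipr (-3.26). The early activation list was called in Th17, with 7 of 15 genes higher, 11 when adjusted over the list alone (set adjusted p 0.0048), and in the difference between cultures (0.0218).

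Hif1a ko lowered glycolysis and hypoxia genes in both cultures. In Th17 Bnip3 fell from 69.9 ± 0.00589 to 0.952 ± 0.133 (n = 2 each; adjusted p 3.89e-08), Slc16a3 from 187 ± 2.05 to 7.70 ± 0.0414, Slc2a3 from 69.7 ± 10.5 to 7.93 ± 0.959 and Tpi1 from 800 ± 183 to 120 ± 23.7. In Th0 Bnip3 fell by 4.47, Slc16a3 by 3.88 and Tpi1 by 2.55. H2-Ab1 of the B cell list fell with them, by 4.81 in Th17 and 4.01 in Th0. Of 22 genes in the glycolysis list, 18 fell in Th17 (22 when adjusted over the list alone; set adjusted p 0.000228) and 16 in Th0 (20; 1.3e-05). Th17 list genes were not called in either culture, with 1 lower in Th17 when adjusted over the list alone. Hif1a over the whole gene was not called (log2 change -0.32). In Th17 220 genes were called, 6 higher and 214 lower (102 to 142 without 1 library), and in Th0 75, 10 higher and 65 lower (34 to 48). Both cultures shared 63 lower genes, where 1.32 were expected. No gene was called by limma for the difference between cultures, with 60 at an unadjusted p under 0.05, and 1 was called without Th0 ko replicate 2.

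**Figure D2:**
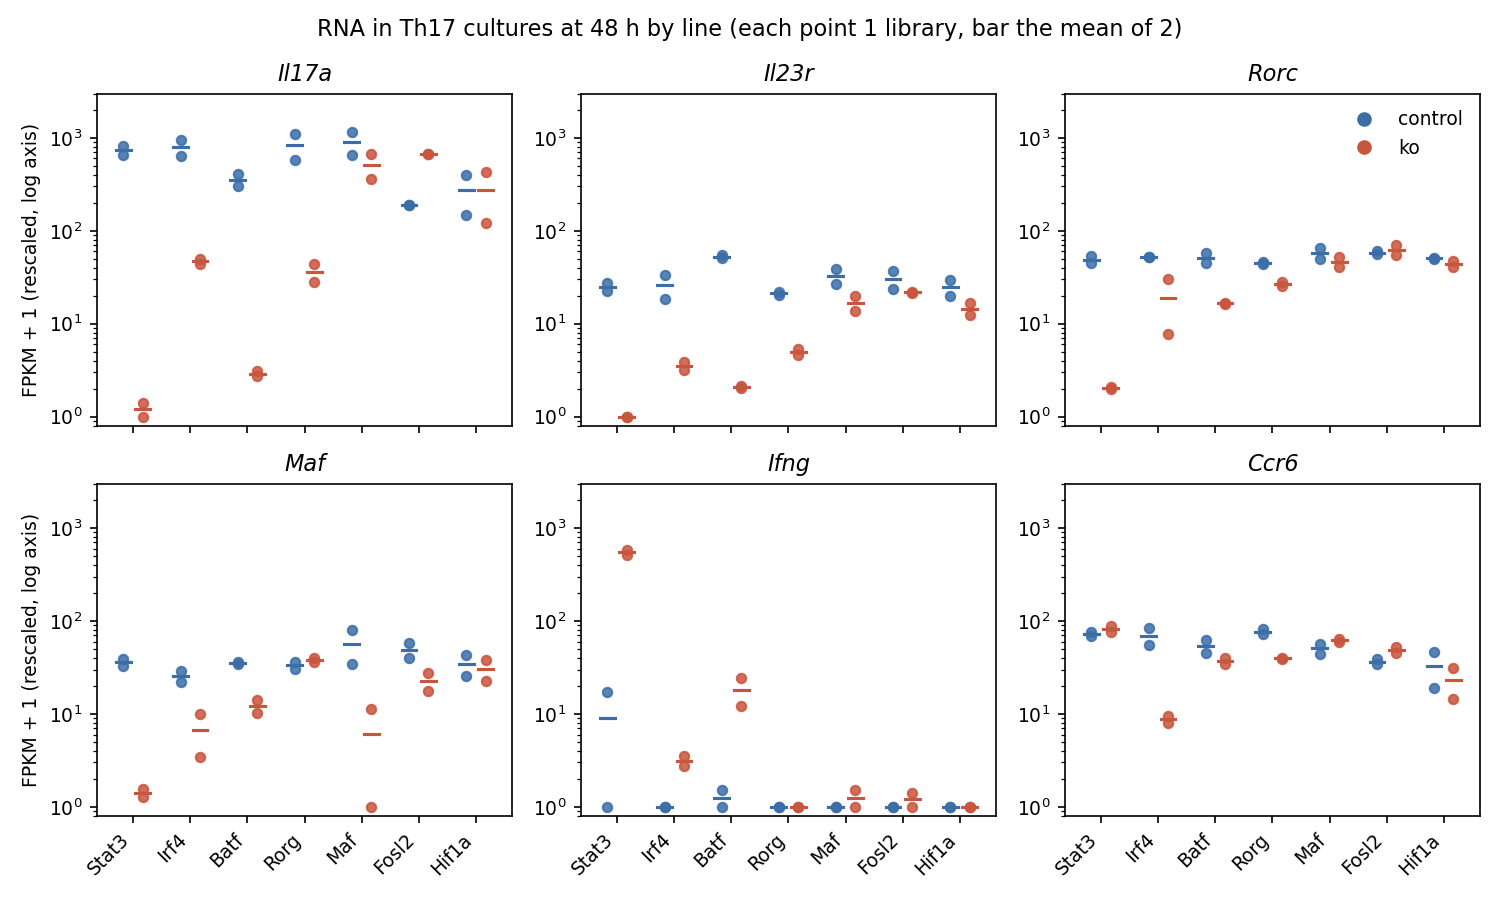
FPKM plus 1 (log axis) of Il17a, Il23r, Rorc, Maf, Ifng and Ccr6 in Th17 cultures at 48 h, 1 point per library, with control and ko libraries of each of the 7 lines side by side and bars at the mean. Il17a and Il23r are lowest in Stat3 ko, Ifng is highest there, and Ccr6 is lowest in Irf4 ko.

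Genes raised in Th17 at least 2-fold in the controls of the other lines fell most in Stat3 ko, by a median of 1.39 on the log2 scale, with 220 of 351 called lower and 7 higher. The median fell by 0.919 in Irf4 ko (109 lower and 3 higher of 354), by 0.614 in Batf ko (59 and 7 of 342), by 0.509 under the Fosl2 ko label (60 and 8 of 324) and by 0.415 in Hif1a ko (51 lower of 361). In Rorg ko the median was 0.134 (4 lower of 358), but -0.135 without control replicate 2 and -0.039 without ko replicate 1. In Maf ko it was -0.052 (1 lower of 343), but 0.046 without control replicate 1. With an estimated correlation no set was called, the lowest adjusted p being 0.0767 for Stat3 ko, and with the preset correlation all 7 were. Calls of the lines overlapped: 244 genes fell in both Irf4 and Stat3 ko, where 39.5 were expected, 137 in Batf and Stat3 ko (20.5 expected) and 98 in Batf and Irf4 ko (9.75 expected). The numbers that rose in both were 116 (22.0 expected), 73 (8.05) and 53 (6.07). The lines share 1 estimate of spread per gene, so these overlaps are not independent tests.

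Th1, Th2 and iTreg cultures were compared with Th0. Their libraries were wild type, from library series 2 and 4. Of the Th0 libraries 1 was wild type, and the rest were controls of knockout lines from more series. The fit of 38 libraries had no term for line or series, so the differences from Th0 may hold effects of both. In Th1, Tbx21 stood at 33.9 ± 0.481 (n = 2) against 0.764 ± 0.376 in Th0 (n = 16; adjusted p 1.07e-17), Ifng at 28.3 ± 7.03 against 0.575 ± 0.966 and Gbp2 at 272 ± 97.8 against 22.1 ± 7.45. In iTreg, Nt5e rose by 4.24, Ikzf4 by 3.21, Lrrc32 by 2.64, Il9 by 5.91 and Ccr6 by 2.05, and Wisp1 fell by 2.86. The marker Nkg7 rose by 2.20 (adjusted p 0.132 without iTreg replicate 1). In Th2, Il13 stood at 96.1 ± 15.9 against 8.87 ± 17.4 (adjusted p 3.91e-05) and Gata3 at 64.9 ± 18.2 against 18.5 ± 8.09 (adjusted p 0.00021), but neither was called without Th2 replicate 1 (adjusted p 0.0724 and 0.764). Of the Th0 libraries compared, Irf4 control replicate 2 lay apart, with Gata3 at 46.8 and Il13 at 74.0 (11.8 to 21.4 and 2.27 to 8.36 in the others). Th2 replicate 2 stood near it, at 52.1 and 85.1. The library was kept as a Th0 control, and without it both genes stayed called. Of 10588 genes, 73 were called in Th1 (69 higher and 4 lower; 22 without Th1 replicate 1), 56 in Th2 (36 and 20; 1 without Th2 replicate 1 and 124 without Th2 replicate 2) and 937 in iTreg (505 and 432; 395 without iTreg replicate 1 and 611 without iTreg replicate 2). In Th1 the set tests called the Th1 list (4 of 13 higher, 5 adjusted over the list alone; set adjusted p 0.000662) and the interferon list (4 of 12, 8; 0.00153). In Th2 the Th2 list was called (5 of 8, 5; 8.2e-05). In iTreg the Treg list (7 of 11, 8) and the transforming growth factor beta list (5 higher and 1 lower of 8, 6 and 1) were called, each with a set adjusted p of 0.000516.

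The siRNA screen lowered candidate regulators in Th17 cultures at 24 h. The siRNA against Rorc brought Il17a to 6.61 ± 1.92 (n = 4) from 67.3 ± 39.4 (n = 6; adjusted p 2.48e-08), and lowered Il1r1 by 2.13, Il22 by 1.88 and Il23r by 1.60. Il17a also fell with siJmjd3 (by 2.12) and siBcl11b (by 1.41), the latter with an adjusted p of 0.0512 without siNonTarget2 replicate 6. Il17f fell with siBcl11b by 1.38, with siRorc by 0.84 (adjusted p 0.0983 without siRorc replicate 3) and with siJmjd3 by 0.83 (adjusted p up to 0.299 without 1 siJmjd3 library). Over all 20 siRNAs, Il23r was lowered by 4, Ccl20 by 4, Il22 by 3 and Rorc by 2, and Tbx21 was lowered by 5 and raised by 1. Foxp3 was called with no siRNA and Ifng was too low to test. Of 19 measured targets, 13 were lower with their own siRNA when adjusted over the 19 targets alone, and 11 over all genes, without Atf6 (adjusted p 0.128) and Ddit3 (0.938): Aes (-2.47), Sirt2 (-1.65), Satb1 (-1.17), Prkrir (-1.06), Ski (-0.82), Ccr6 (-0.65), Lef1 (-0.61), Nfatc2 (-0.50), Atf6 (-0.46), Bcl11b (-0.45), Rorc (-0.42), Ddit3 (-0.37) and Kdm6b, the target of siJmjd3 (-0.36). Calls of Ski (without siSki replicate 1), Ccr6 (without siNonTarget2 replicate 3 or siCcr6 replicate 2 or 3), Nfatc2 (without siNonTarget2 replicate 5 or either siNfatc2 library) and Kdm6b (without either siJmjd3 library) were lost, with adjusted p up to 0.229, 0.193, 0.482 and 0.286. Egr2, Zfp36l2, Jmjd6, Trib3, Id2 and Inhba were not, and Crem was not measured. In total 9531 gene and siRNA pairs were called (6316 without siNonTarget2 replicate 6). All siRNAs share those 6 control libraries, so their effects are not independent. The code 120309, carried by libraries of siId2, siSki, siAtf6, siTrib3, siPrkrir, siSatb1 and siRorc, held no control library. Without the term for the codes in the labels 2354 pairs were called, 2159 of them with siBcl11b. There siJmjd3 fell from 1783 to 23 and siSatb1 from 500 to 0.

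The siRNA against Rorc was tested in both sets. In the screen 1008 of 9974 genes were called, 507 higher and 501 lower, with 223 without siRorc replicate 3, 627 without siRorc replicate 2, 658 and 619 without siNonTarget2 replicate 1 and 2, and 60 without the code term. In the RPMI set 40 of 9939 were called, 16 higher and 24 lower, with 12 without siRorc replicate 1 and 15 without siRorc replicate 2. There Il17a stood at 15.8 ± 0.132 against 136 ± 9.44 (n = 2 each; adjusted p 4.8e-06), Il1r1 fell by 1.68 and Il22 by 2.21, and Tbx21 rose by 0.66. Of the 9796 genes tested in both, 27 were called in both, all in the same direction, where 3.95 were expected. The Th17 list was called in both sets, with 9 of 21 genes lower and 1 higher in the screen (11 and 1 adjusted over the list alone; set adjusted p 0.0307) and 5 of 22 lower in RPMI (11; 0.0227). No other RPMI siRNA had its own target called by limma. The log2 changes were -0.17 for Etv6 (adjusted p 0.60), -0.15 for Jmjd6 (0.56) and 0.20 for Kdm6b, the target of siJmjd3 (0.997). Results with these siRNAs therefore do not show what loss of their targets does. Of the other RPMI siRNAs, siJmjd3 called 2 genes, both lower, among them Il17a (69.1 ± 5.55; adjusted p 0.044, lost without any 1 library), with Kdm6b not called. That count was 19 without siCntl replicate 1, 4 without siCntl replicate 2 and 0 without either siJmjd3 library, and the set tests called the Th17 list (1 of 22 lower, 7 adjusted over the list alone; 0.0239) and early activation (0 of 14, 7 higher; 0.0455). By limma siEtv6 and siJmjd6 called 0 genes, with 802 and 880 at an unadjusted p under 0.05 and 25 and 15 called without siCntl replicate 1, 6 and 2 without siCntl replicate 2, and 1 and 4 for siEtv6 without its replicate 1 and 2.

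ChIP in knockouts asked whether factors need each other on DNA. IRF4 peaks depended on Batf: of the 1000 highest control peaks, 41.9% ± 5.5 had a summit within 100 bases in Batf ko Th17 (SD over 4 pairs of 2 control and 2 ko libraries), against 97.1% in the other control library. In Th0 the shares were 39.3% ± 8.9 and 92.8%. BATF peaks depended less on Irf4, with 77.1% ± 2.5 found in Irf4 ko Th17 and 67.3% ± 6.0 in Th0, against 98.0% in the other control in both. IRF4 (97.0% ± 0.6 against 96.6%) and STAT3 peaks (92.2% ± 3.2 against 91.1%) were found in Rorg ko as often as in the other control. H3K4me2 peaks were found in Rorg ko in 84.7% and 74.1% of cases when ko and control had the same replicate number, and in 65.2% and 67.7% otherwise, against 69.2% in the other control. For H3K4me3 the shares were 88.0% and 80.0%, 67.7% and 63.4%, and 65.4%, so that only unmatched pairs compare with the other control. Peaks of the cofactor p300, with 1 library each, were found in 94.3% of cases in Rorg ko (Wilson 95% interval 92.7 to 95.6), 71.6% in Batf ko (68.7 to 74.3), 63.0% in Irf4 ko (60.0 to 65.9) and 50.6% in Stat3 ko (47.5 to 53.7). The p300 ko lists held 20538, 11943, 6919 and 4182 peaks in that order. The background, in controls of other lines at the length of the ko list, was 85.7% to 88.8% for the Rorg control, 87.6% to 89.9% for Batf, 81.8% to 89.5% for Irf4 and 73.2% to 84.8% for Stat3. With all 4 ko lists at 4182 peaks, chosen after the data were seen, the shares were 93.0%, 63.0%, 58.6% and 50.6%. The intervals cover counting error over peaks alone. In knockouts of the factor itself, 0.9% (IRF4) to 7.8% (c-Maf) of wild-type peaks were found, in lists of 137 to 1478 peaks.

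**Figure D3:**
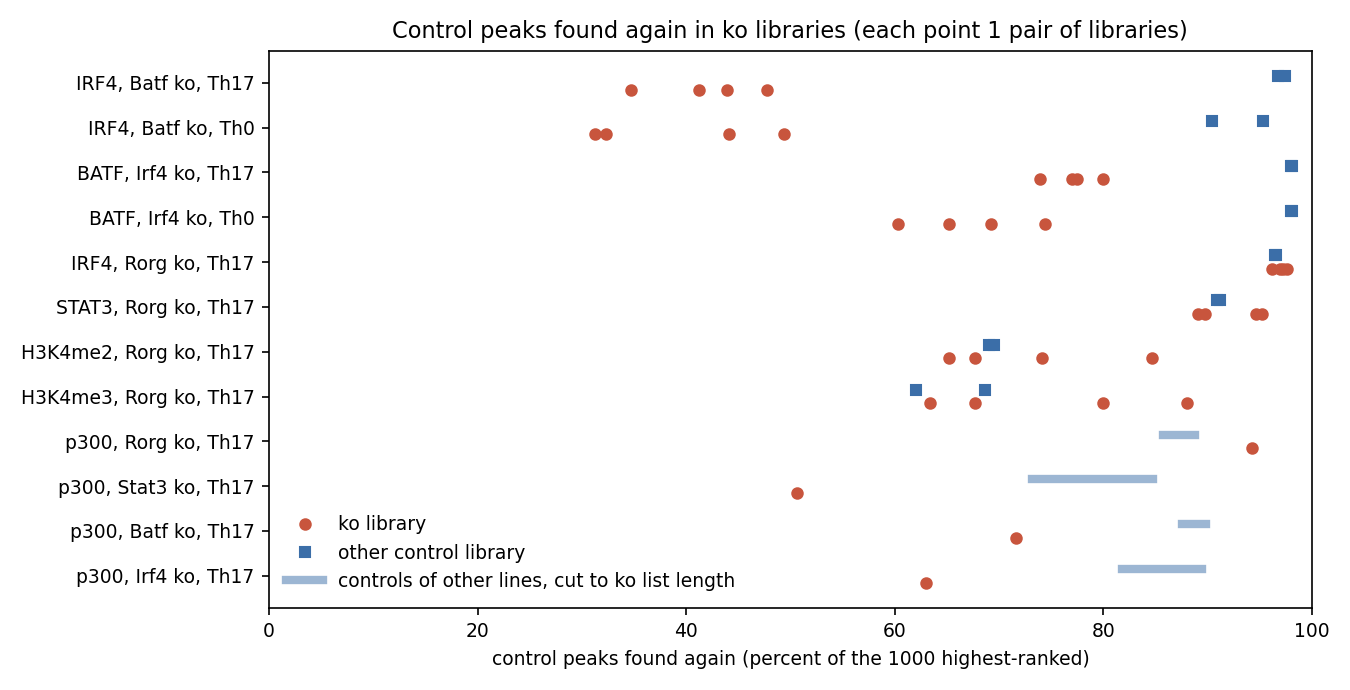
Percent of the 1000 highest control peaks with a summit within 100 bases in the ko library (points, 1 per pair of libraries) and in the other control library or, for p300, in the controls of other lines at the length of the ko list (range). IRF4 peaks in Batf ko lie at 34.7% to 47.8% in Th17, and STAT3 and IRF4 peaks in Rorg ko lie at the level of the other control.

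Factors differed in how far their Th17 peaks were present in Th0. The share found in Th0 was 99.5% for CTCF, 89.8% for Fosl2, 85.6% for BATF and 78.9% for IRF4, but 34.2% for RORg, 34.1% for p300, 5.2% for STAT3 and 3.1% for c-Maf. Replicate Th17 libraries shared 87.1% of RORg, 91.2% of STAT3, 95.4% of c-Maf and 99.4% of BATF peaks. In wild-type Th17 libraries without a time of their own (typically 48 h by the protocol), 64.8% of STAT3 and 59.9% of IRF4 peaks were present at 3 h, and 77.6% and 87.1% at 16 h. Among the 3000 highest peaks, 88.2% of BATF summits had an IRF4 summit within 100 bases and 93.5% of IRF4 summits a BATF summit, against 0.3% and 0.2% for CTCF. List lengths differ between libraries, which these shares do not correct. The Th0 lists held 85 c-Maf, 368 STAT3, 1809 RORg and 483 and 1396 p300 peaks, so most of 1000 c-Maf or STAT3 peaks could not have been found.

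At single loci the same sites recurred. Downstream of Il17a a site held STAT3 peaks ranked 21 and 19 in the wild-type libraries (summits 20730910 and 20730907) and p300 peaks ranked 4 and 4 (20730891 and 20730887). Within Rorc, 10830 and 10845 bases from the transcription start, STAT3 peaks ranked 3 and 7 (summits 94187577 and 94187592), and they were present in Rorg ko at ranks 8 and 16. Within Il21, 1210 and 1222 bases from the start, STAT3 peaks ranked 18 and 23. Within Il23r, RORg peaks ranked 8 and 7 (67433333 and 67433335). At Il17a the H3K4me3 libraries had 7 and 6 peaks in the Rorg control and 2 and 1 in Rorg ko, and the score of the highest fell from 3100 in both to 216 and 198, the last at another position. At Il17a, Il17f, Il21, Il1r1, Maf, Rorc and Ccl20, Stat3 ko had no p300 peak, and at Il23r it had 1. Its p300 list held 4182 peaks against 8025 in its control. STAT3 peaks were absent from all these loci in Stat3 ko, which follows from the loss of the factor and is no result about a locus.

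Genes changed in a ko carried peaks of the factor more often than other tested genes for 5 of 7 factors, by Fisher's exact test (two-sided). The share was 77.5% against 33.8% for Hif1a (odds ratio 6.75, adjusted p 5.41e-38), 22.9% against 13.1% for STAT3 (1.97, 1.35e-20), 87.3% against 77.8% for Fosl2 (1.96, 1.75e-09), 93.2% against 86.9% for BATF (2.06, 0.000291) and 74.7% against 69.0% for IRF4 (1.33, 0.000616). For Hif1a, 169 of 212 lower genes carried a peak and 0 of 6 higher genes. For RORg 4 of 7 changed genes carried one (odds ratio 3.36, adjusted p 0.125), and for c-Maf 1 of 2 (0.686, adjusted p 1). Genes are not independent replicates, and long or active genes collect more peaks.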

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

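The counts over other splits of the samples, and the count of genes near Fosl2, were planned before the results they test were seen. All other tests of explanations in this part were chosen after the result was seen.

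In the groups of 4 to 10 samples, 20 tests were made for a sample far from the others (10 measures in 2 groups of the siRNA screen), and 4 of them found one. In 1 of the 4, Il22 in siRorc, 3 values of 0 fixed the outcome, so 3 of 19 remain, where chance finds about 1 in 20. Among the 6 siNonTarget2 libraries, Rorc was highest in replicate 5 at 75.75 FPKM and Il22 highest in replicate 6 at 6.03 FPKM. Among the 4 siRorc libraries, Il22 stood at 0.39 FPKM in replicate 1 and at 0 in the others, and 7598 genes were listed at 0 in replicate 3.

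Effects of a knockout that differed between Th17 and Th0 cultures, by a test of the difference itself, came to 12 genes for Batf, 58 for Irf4, 253 for Stat3, 2 for Maf and 9 for Fosl2. These counts come from the pooled fit, which keeps the library labelled Th0 Maf ko replicate 2, weighed next. The Maf difference therefore rests on a Th0 group that holds this library. Without it the counts for Batf, Irf4, Stat3 and Fosl2 were higher, as given with the knockout lines. For Rorg and Hif1a the limma test called 0 genes, with 58 and 60 at an unadjusted p under 0.05, where 528 were expected by chance. These 0 calls therefore do not show equal effects in both cultures.

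The first pattern weighed is that of the library labelled Th0 Maf ko replicate 2. Over 271 genes raised in Th17 in the other lines it lay 95.2% of the way from the Th0 to the Th17 Maf control, where the highest other Th0 library lay at 38.6% and the Th17 Maf ko libraries at 94.1% and 97.0%. The lowest Th17 library, Stat3 ko replicate 2, lay at 10.1%, so the ranges of the Th0 and Th17 labels overlap on this scale. Loss of Maf in a Th0 culture is argued against by the other library with that label, which lay at 0%. A mixture with Th0 cells is argued against by the share of Th0 that 65 genes lower in Th17 would need, 0.7% (interval 0.5 to 1.0). A Th17 culture under a Th0 label is the explanation left open and fits these values, and the library was closest to Th17 Maf ko replicate 2 (SD of the log2 differences 0.173, against 0.204 for the next closest pair of 48 h libraries).

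The second pattern is that libraries labelled Fosl2 ko differed from their controls in 694 genes in Th17 but not in Fosl2, whose log2 change was 0.20. A swap of ko and control in a single pair is argued against, since it would turn the sign of the relation between pairs. The ko minus control differences of the 2 pairs went together over genes (correlation 0.742, across genes, which are not independent). A swap in both pairs would leave that correlation unchanged, so the test cannot decide on it. A strain variant beside Fosl2 that acts only on its neighbours is argued against as the whole cause, since most calls lie elsewhere. Of 113 tested genes within 10 megabases of Fosl2, 15 were called, against 679 of 10455 elsewhere (odds ratio 2.203, Fisher's exact p 0.01093). Genes near Fosl2 were thus called more often. The count cannot test a linked variant that changes genes elsewhere. A variant behind part of the calls may add to them. Loss of the protein with the transcript kept stays open as a biological explanation, since the labels do not give which part is deleted and FPKM over the whole gene cannot show it.

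The third pattern is the lower number of genes at 0 in siRorc replicate 3, 7598 against 9470 to 10749 in the other 48 screen libraries. The siRNA itself is argued against, since its other libraries listed at least 10009 genes at 0. Reads from an abundant other cell type are argued against: of 8698 genes at 0 in the other libraries, 1498 were above 0 here, with a median of 0.137 and a highest value of 0.6788 FPKM, and 10 of 40 marker genes of 5 other cell types stood above all other libraries by at most 0.193 FPKM (Csf1r). A deeper library would keep the sum over genes with a mean under 1 within the range of the others, since FPKM divides by depth. The sum was 1189 against 606 to 1091 elsewhere, above that range but short of the limit set for arguing against depth. The files give no depth, so a deeper library stays open. Without this library siRorc called 223 genes in place of 1008.

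Other splits of the same samples show how often a grouping by chance gives as many genes. For Th17 against Th0 at 48 h, 1 of 100 splits called as many genes as the real one, itself. It called 6203 genes and the others at most 2. The splits were not drawn within lines, and every other split leaves the Th17 effect in the spread, which lowers its count. The low counts of the others therefore do not settle how often chance gives as many genes. For siRorc in the screen, 1 of 100 splits drawn from 210 called as many, itself, with 1008 genes, but the highest other called 1007 and 6 others at least 100. Within the codes that both share, that split is the real contrast turned round, and the splits were not drawn within codes. Without the code term siRorc called 60 genes. At 16 h only 10 splits exist, too few for a share under 0.05; 1 of them, the real one, called 1812 genes and the highest other 2.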

How the results depend on the processing

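Other summit distances, p300 ko lists at one length, the fit of the Th17 libraries alone and leaving out the libraries labelled Th0 Maf ko replicate 2 and Th0 Irf4 control replicate 2 were chosen after the data were seen. Counts of called genes are taken as unchanged within 1.5 times the count in the report. Except where a cause is given, the cause was not tested. Of the planned settings, fits for counts and overlap by 1 base were not run, since the files hold neither counts nor peak widths.

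The 48 h comparison of Th17 with Th0 and the 13 own targets lowered stayed within 1.5 times their counts under every setting run. Leaving out each line gave 5603 to 6170 genes and each screen library 12 to 13 targets, and without the code term 9 targets were lowered. With a pseudocount of 0.1, Batf ko called 31 genes in Th0 and the Irf4 difference between cultures 38. Without the filter on low values Batf ko called 670 (Th17), 173 (Th0) and 107 (difference), Irf4 ko 716 (Th0) and 228 (difference), and Stat3 ko 5 (Th0). Rorg ko called 35, 3 and 5, Maf ko 20 (Th17) and 1 (difference), Fosl2 ko 53 (Th0) and 135 (difference), and the Hif1a difference 3. Th1 then called 127, Th2 103, RPMI siEtv6 2 and RPMI siJmjd3 0.

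With values as deposited Rorg ko called 0 in Th0, Maf ko 1, 7 and 1 (Th17, Th0, difference) and RPMI siJmjd3 1, and the Th17-raised genes in Stat3 ko (-1.369) passed the threshold. With quantile normalization Maf ko called 1 in Th17 and 1 for the difference, and RPMI siJmjd3 4. Calls under the Fosl2 ko label were 59.3% higher with values as deposited and 49.9% with quantile normalization, against 41.8% in the report.

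With the library series as a block, counts rose in most knockouts: Batf 1.0e+03 (rounded), 150 and 95 (Th17, Th0, difference), Irf4 1875, 870 and 378, Stat3 2385 (Th17) and 663 (difference), Rorg 21 (Th17), Maf 20, 27 and 8, Fosl2 2050, 34 and 113, Hif1a 489 (Th17) and 220 (Th0), and iTreg 1579. Without the code term siRorc called 60 and all pairs 2354, of which 2159 with siBcl11b. The RPMI replicate numbers are shared but not stated to pair cultures. As a replicate block they gave 1 gene for siJmjd3 and 44 for siRorc, and the deviations of siCntl libraries from their mean correlated with those of the siRNAs at -0.256, -0.419, 0.11 and -0.159 across 9895 genes, and those of the siRNAs with each other at 0.323 (siEtv6 and siJmjd3), 0.276 (siEtv6 and siRorc), 0.254 (siJmjd3 and siRorc), 0.061, 0.054 and 0.003 (with siJmjd6).

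In fits of a comparison's own libraries, with fewer samples, the Batf difference called 105, Irf4 ko 2, 73 and 0, Stat3 ko 5 (Th0) and 520 (difference), Rorg ko 2 (Th17) and 0 (Th0), Maf ko 0, 0 and 1, Fosl2 ko 1571 (Th17) and 119 (difference) and the Hif1a difference 2. Without the library labelled Th0 Maf ko replicate 2, the Batf difference called 51, Irf4 178, Stat3 393 and Fosl2 29, Rorg ko 2 in Th0 and Maf ko 18 in Th17. The Th17-raised genes in Irf4 (-0.921) and Stat3 ko (-1.391) then passed the threshold. Without the library labelled Th0 Irf4 control replicate 2, the Th17, Th1, Th2 and iTreg comparisons with Th0 stayed within 1.5 times their counts. The Th17 libraries alone gave 5 for Maf and 419 for Fosl2 ko. Calls were lost for Fam124b in Rorg, Maf in Maf, Cd68 under the Fosl2 ko label and Stat3 in Batf ko. With the preset correlation the Th17-raised genes passed the threshold in all 7 lines at unchanged medians (Batf -0.614, Irf4 -0.919, Stat3 -1.391, Rorg 0.134, Maf -0.052, Fosl2 -0.509, Hif1a -0.415), since the preset is smaller than the estimate.

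Leaving out 1 of a comparison's own libraries, which tests fewer samples, gave these lowest and highest counts for Th17, Th0 and the difference: Batf 113 to 211, 14 to 32 and 0 to 4; Irf4 472 to 1392, 153 to 268 and 27 to 288; Stat3 700 to 1068, 1 to 2 and 110 to 168. For Rorg they were 2 to 8, 0 to 1 and 0 to 1, for Maf 1 to 5, 0 to 933 and 0 to 511, for Fosl2 86 to 325, 2 to 5 and 2 to 11, and for Hif1a 102 to 142, 34 to 48 and 0 to 1. At 16 h they were 970 to 1646, in Th1 22 to 90, in Th2 1 to 124 and in iTreg 395 to 1066. In the screen siRorc gave 223 to 1176 and all pairs 6316 to 11716, and in RPMI siEtv6 gave 1 to 25, siJmjd3 0 to 19, siJmjd6 0 to 15 and siRorc 12 to 55. The median of Th17-raised genes changed sign in Rorg ko (-0.135 to 0.37) and Maf ko (-0.148 to 0.046).

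Of 181 named gene results, none that was called reversed. Those that changed sign were not called: Il21 in Rorg ko (-0.36 to 0.25 without 1 library), and own targets in the screen. These were Id2 (-0.04) and Jmjd6 (-0.21) without the code term, and, without 1 library, Jmjd6 (-0.01 to 0.05), Trib3 (-0.21 to 0.29) and Zfp36l2 (-0.21 to 0.01). Calls were lost 10 times without the code term, 27 times in the comparison's own libraries and 12 times with a pseudocount of 0.1.

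For peaks, the order of p300 shares over Rorg, Batf, Irf4 and Stat3 ko is also the order of the ko list lengths (20538, 11943, 6919 and 4182). With the 4 ko lists at 4182 peaks the shares were 93.0%, 63.0%, 58.6% and 50.6%. Within 50 bases IRF4 peaks were found in 32.8% (Batf ko Th17), 30.3% (Batf ko Th0) and 95% (Rorg ko) of cases, BATF in 73.9% (Irf4 ko Th17) and STAT3 in 84.3%. Within 250 bases the values were 47.9%, 97.9% (IRF4 in Rorg ko), 79.6% and 83.1% (H3K4me2). Within 500 bases they were 52.1%, 49.0%, 98.7%, 81.9%, 97.0% (STAT3), 89.6% (H3K4me2) and 90.0% (H3K4me3). For p300 in Rorg, Batf, Irf4 and Stat3 ko they were 89.7%, 61.2%, 50.8% and 37.8% within 50 bases, 96.5%, 76.8%, 67.5% and 56.8% within 250, and 98.0%, 80.1%, 71.1% and 60.9% within 500. A wider window finds more by construction. With 3000 control peaks, which adds weaker ones, p300 gave 91.5%, 66.0%, 56.3% and 40.3%, BATF 72.0% (Th17) and 50.9% (Th0), and in Rorg ko IRF4 96.0% and STAT3 83.7%. With 300 they were 98.3%, 80.0%, 72.0% and 61.7% for p300, 80.4% for BATF in Th0 and 99.3% for IRF4 in Rorg ko. With the 3000 highest peaks of each library the odds ratio for RORg was 7.089 and passed the threshold. Depth is not given in the files, so what it limits cannot be stated.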

Other observations

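All tests and fits in this part were chosen after the results were seen.

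A smaller share of IRF4 control peaks was found in Batf ko than of BATF control peaks in Irf4 ko. A hypothesis is that the sites where IRF4 needs BATF are also those where BATF needs IRF4, which may be joint sites. In the 4 control libraries, sites bound by both factors that lost IRF4 in Batf ko also lost BATF in Irf4 ko in 27.8% and 27.6% (Th17) and 40.0% and 33.2% (Th0) of cases. Sites that kept IRF4 lost BATF in 4.9%, 6.8%, 19.8% and 14.7%, and the lowest difference was 18.5 points. Weaker BATF peaks at the lost sites as the whole cause are argued against by the odds ratio within 4 ranges of the BATF peak rank, which was at least 2.67. Sites within a library are not independent replicates.

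In a fit of the 28 Th17 libraries of the 7 lines alone, without the spread of Th0 libraries, Batf ko lowered Il17f (log2 change -3.44, adjusted p 2.6e-05) and Rorc (-1.60, 0.0205). Irf4 ko lowered Il17a (-4.04, 9.4e-05), Il17f (-3.67, 9.71e-06) and Il21 (-2.51, 0.00295), and Rorg ko lowered Il17a (-4.51, 0.000385), Il17f (-2.52, 0.00557) and Il23r (-2.08, 0.00135). The same fit lost the calls of Maf in Maf ko (adjusted p 0.0523), Stat3 in Batf ko (0.0524), Fam124b in Rorg ko and Cd68 under the Fosl2 ko label.

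The Ikzf3 line had 1 library per genotype and culture and entered no test of its own. In Th17, Ikzf3 stood at 6.83 FPKM as deposited in ko and 13.0 in the control, Il10 at 11.8 and 25.8, Il9 at 119.9 and 31.97, Ccl20 at 127.4 and 50.7, Il2 at 717 and 308, Il17a at 1060 and 896, and Rorc at 67.0 and 56.3. These genes were picked after their values were seen.

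The authors' tables rest on read counts, and their deposited adjusted p called 156 genes in Th17 for Batf, 136 for Irf4, 150 for Stat3, 78 for Rorg, 83 for Maf, 93 for Fosl2, 142 for Hif1a and 47 for Ikzf3. A single Benjamini-Hochberg adjustment of the deposited p-values called 228, 205, 255, 119, 133, 169, 134 and 47. In 21 of the 29 tables the deposited count was lower than after a single adjustment. In their mean counts, Il17a stood at 690.5 in Rorg ko against 15579 in its control, and at 17473.5 against 4500.5 under the Fosl2 ko label.

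Over all genes, the most similar pair of RNA libraries was Th17 16 h replicates 2 and 3 (correlation 0.997, across genes). The labels do not say whether replicates come from separate cultures.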
